A study of Medicago truncatula with 12 samples.

How the data were processed

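Polyadenylated RNA of whole Medicago truncatula A17 roots was sequenced after Illumina TruSeq library preparation, per the labels' protocols, from samples with an RNA integrity number above 8. The 12 libraries were assigned to 4 groups of 3 from their titles: mock or S. meliloti inoculation, each without or with 100 mM NaCl. The titles call the samples biological replicates A to C, and the series text gives 21 plants for each.

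The authors deposited a table of raw counts per gene identifier and a table of FPKM values (fragments per kilobase, scaled to the mapped total), with one column for each of the 12 libraries and none pooled. The submitters' processing notes name FastQC, TopHat2 2.0.13, Subread and edgeR without their roles. The genome build, annotation, strand setting and handling of reads that map to several places are not given in the sources used here, so genes with near-identical copies may share or lose counts. The deposited count values were whole numbers, and every column belonged to one of the 12 samples. The count table held 50443 identifiers, and 50444 were in the FPKM table. Neither table pairs identifiers with gene names. A RefSeq gene table of assembly MtrunA17r5.0-ANR was searched for names, and 0 identifiers matched. The 19 gene lists to be built from product descriptions therefore could not be made and were not used.

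Total counts ran from 16106273 to 22222289 per library. Replicates of a group were compared by a chi-square statistic per degree of freedom over genes with a summed count of at least 20. It ran from 11.5 to 40.2 over the 12 within-group pairs, above sampling noise, so no library was taken as a copy of another.

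Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group were kept (22816), libraries were scaled by TMM, and one quasi-likelihood model with a mean per group was fitted to all 12 libraries. The 5 planned contrasts were salt in mock roots, salt in inoculated roots, rhizobium without salt, rhizobium with salt, and the difference of the rhizobium effects. A gene was called at a two-sided p under 0.05 after Benjamini-Hochberg adjustment over all tested genes. CPM values used TMM-scaled library sizes. Standard errors were derived from the quasi-likelihood F statistic. A fold against a group with 0 counts was set against a floor of 3 counts summed over the group, and with 1 to 3 counts a ratio is given with an exact binomial interval of 95%. Floors and intervals cover counting error only.

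Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists in each contrast. Fry asks whether a list moves one way and does not compare it with other genes. The early nodulation and infection list (28 identifiers) and the Nod factor perception and common symbiosis signalling list (13) were fixed before the data were examined, as were the contrasts, tests, thresholds and most of the other settings. Lists for autoregulation (4), leghemoglobins (11), arbuscular mycorrhiza (5), root apical meristem (5) and further receptors, channels and nodule development (10) were written after the identifiers were seen and before any test, and mycorrhiza and meristem genes share pathways or tissue with nodulating roots. The identifiers in all lists rest on published assignments as remembered, which could not be checked here.

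Named genes followed a rule: for each contrast, the 8 largest rises and falls among called genes with an average log2 CPM of at least 2 and no overlap between the compared groups, and the members of both fixed lists. Because identifiers have no names here, only a few are printed per comparison, and which of them to print was settled after their values were seen. The 1 gene that fell with rhizobium in salted roots is named because the count is small.

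The replicate letters are shared by all groups. The series text speaks of each treatment from a biological replicate but names no shared day or batch. Deviations from group means were therefore correlated between libraries with the same letter. Letters were taken to pair the samples of a contrast where every correlation was over 0.1. That held for rhizobium with salt (0.234 to 0.399) and salt in inoculated roots (0.114 to 0.262). It did not hold for rhizobium without salt (0.0693 to 0.524) or salt in mock roots (-0.134 to 0.239). The rule reads the data and cannot show whether the design paired the samples, and the main fit holds no letter term.

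The other settings chosen then were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors within edgeR, no low-count filter beyond 1 count, a filter of 1 CPM in 3 libraries, a fit of the 6 compared libraries, the replicate letter as a block, a robust fit, an adjusted p under 0.01, at least a 2-fold change, and each library left out in turn. Limma 3.58.1 was also run with a trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, and on log2(FPKM + 1) without that filter. Folds on these scales understate the change of low genes. DESeq2 gave no adjusted p for 37 genes in the contrast of rhizobium without salt. The average rhizobium effect, the average salt effect, the overlap of the salt responses and the permutations of salt labels were added after the data were seen.

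The edgeR steps were tested on counts simulated from the real means, library sizes and dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had an average log2 CPM of at least 0. Genes were simulated independently and without a letter effect. For salt in mock roots 59% and 90% were recovered, for rhizobium without salt 64% and 93%, for rhizobium with salt 58% and 93%, and for salt in inoculated roots 71% and 94%. For the difference of the rhizobium effects 24% and 81% were recovered. False calls made up 2.58% to 6.88% of calls.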

Results

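Transcript levels were measured by RNA sequencing in whole roots of the barrel medic Medicago truncatula, accession A17, a legume that forms nitrogen-fixing nodules with the soil bacterium Sinorhizobium meliloti. Seedlings grew in pouches with or without 100 mM NaCl and on day 4 received either S. meliloti strain Rm1021 in 10 mM MgSO4 or the MgSO4 solution alone, called mock here. Roots were harvested 24 hours later, on day 5. The 4 groups, mock without salt, mock with salt, inoculated without salt and inoculated with salt, held 3 biological replicates each, lettered A to C, and each replicate pooled 21 plants. One library, inoculated with salt A, was labelled as a resubmission. Total counts per library ran from 16106273 (inoculated without salt A) to 22222289 (inoculated without salt B), and the 10 most abundant genes took 4.08% to 4.94% of them. The first principal component of log2 CPM held 28.1% of the variance, and all 6 libraries with salt lay above the 6 without salt on it. Mock with salt A was the lowest of these 6 and stood apart on the second component, at 59.5 against -29.3 to 18.2 for the other 11 libraries. The biological coefficient of variation over all libraries was 17.9%. No gene symbols are given, because none of the 50443 gene identifiers in the count table was paired with a name in the sources used here. Genes are therefore described by lists and by a few identifiers.

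**Figure D1:**
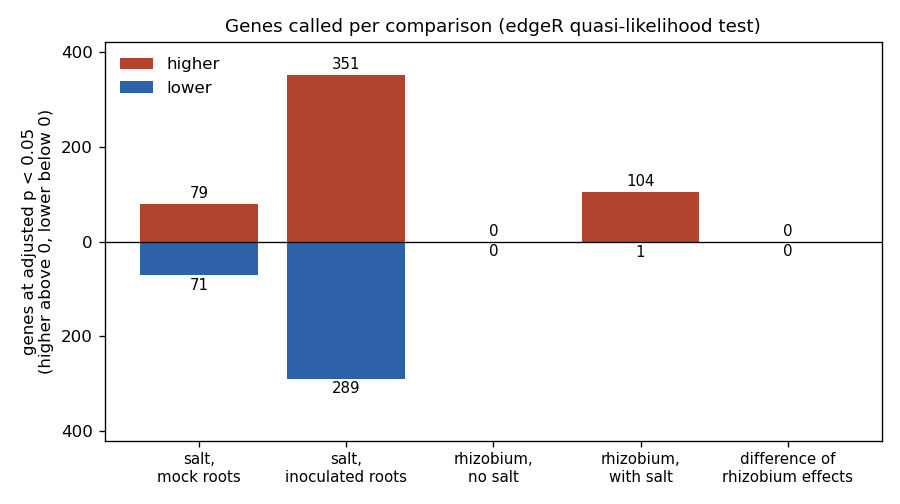
Number of genes called higher (red, above 0) or lower (blue, below 0) in each of the 5 planned comparisons among 22816 genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Salt changed 640 genes in inoculated and 150 in mock roots, rhizobium 105 genes with salt and 0 without, and the difference of the rhizobium effects called 0.

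The salt effect in mock-inoculated roots gave the response to NaCl alone. Salt raised 79 genes and lowered 71. Medtr7g093160 rose by 3.88 log2 units (SE 0.66), from 0.850 ± 0.495 to 12.6 ± 4.73 CPM (SD, n = 3; edgeR adjusted p = 0.0300). Medtr2g020710 fell by 2.63 (SE 0.26), from 174 ± 24.0 to 28.1 ± 8.23 CPM (SD, n = 3; edgeR adjusted p = 0.00274). Medtr3g072520 fell by 2.96 (SE 0.53), from 10.6 ± 1.58 to 1.38 ± 1.30 CPM (SD, n = 3; edgeR adjusted p = 0.0335). These 3 genes had the same sign in inoculated roots, with log2 changes of 2.70 (SE 0.60), -2.21 (SE 0.25) and -3.06 (SE 0.54) and edgeR adjusted p of 0.0392, 0.00405 and 0.0169. Of the 24 tested genes of the early nodulation and infection list, which holds genes of infection thread growth, nodule initiation and their hormone signals, 0 were called by edgeR over all genes. Adjusted over the list alone, 3 were higher and 1 lower. The list as a whole did not stand apart from other genes (camera adjusted p = 0.957). The list of Nod factor perception and common symbiosis signalling genes mostly holds genes that sense the bacterial signal and pass it on. It also holds a few genes of hormone signalling and of the control of nodule number. Of its 12 tested genes, 0 were called over all genes and 3 fell when adjusted over the list alone. That list lay lower than other genes by camera (median log2 change -0.13, adjusted p = 0.0270), a call lost with an estimated correlation (adjusted p = 0.578). It was also lost without mock without salt B or C (camera adjusted p = 0.313 and 0.218) or mock with salt A (0.172), and with the replicate letter as a block (0.0538). An unadjusted p under 0.05 was reached by 2647 genes against 1141 expected by chance. DESeq2 called 378 higher and 328 lower.

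The size of the mock salt response depended on single libraries. With mock without salt A, B or C left out, 10, 11 or 6 genes were higher and 17, 8 or 13 lower. Without mock with salt A, B or C the higher count was 30, 177 or 5, and without C the lower count was 7. Without inoculated without salt C, 32 genes were higher and 37 lower. The call of Medtr7g093160 was lost without mock without salt A, B or C (edgeR adjusted p = 0.101, 0.105 and 0.0960) and without mock with salt A or C (0.0540 and 0.107). The call of Medtr3g072520 was lost without mock without salt A, B or C (edgeR adjusted p = 0.0929, 0.0965 and 0.114), mock with salt B or C (0.0584 and 0.150) or inoculated without salt C (0.0599), and in the fit of the 6 compared libraries alone (0.0613). Medtr2g020710 was called in every alternative run, with edgeR, DESeq2 and limma adjusted p up to 0.0264.

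The salt effect in inoculated roots was read from the 6 inoculated libraries in the same model. Salt raised 351 genes and lowered 289 there. The early nodulation and infection list rose as a whole, with a median log2 change of 0.58 (camera adjusted p = 9.92e-08, and adjusted p = 0.0472 with an estimated correlation). Of its 24 tested genes, 6 rose over all genes by 0.92 to 3.16 log2 units, and adjusted over the list alone 8 rose and 1 fell. Of the 6 calls, 3 were kept without inoculated without salt A, B or C or inoculated with salt A, 4 without mock without salt C or inoculated with salt C, and 5 without mock without salt B or inoculated with salt B. Medtr3g086320 and Medtr6g027840 were called in all 25 alternatives each. Medtr3g086320 rose by 3.16 (SE 0.36), from 0.809 ± 0.230 to 7.33 ± 2.31 CPM (SD, n = 3; edgeR adjusted p = 0.00731). Medtr6g027840 rose by 2.13 (SE 0.30), from 2.09 ± 0.844 to 9.10 ± 2.40 CPM (SD, n = 3; edgeR adjusted p = 0.00819). In the Nod factor list 1 gene rose by 1.40 (its call lost in 6 of 25 alternatives, among them inoculated without salt B or C and inoculated with salt A or C left out, at edgeR adjusted p of 0.0502, 0.0555, 0.0534 and 0.0606), and adjusted over the list alone 2 rose and 1 fell, while the list as a whole did not stand apart (camera adjusted p = 0.962). The 4 genes of the list on autoregulation and systemic control of nodule number had a median log2 change of -0.34 with 0 called over all genes by edgeR (1 fell adjusted over the list alone). Their camera adjusted p was 0.0519, and with the replicate letter as a block it was 0.0284 (adjusted p = 0.127 with an estimated correlation). With no low-count filter their camera adjusted p was 0.0239. Without inoculated without salt B or inoculated with salt A that list's camera adjusted p was 0.0182 or 0.0184.

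In inoculated roots the count also depended on the model. With the replicate letter as a block, 636 genes were higher and 593 lower, and these held 349 of the 351 and 287 of the 289. The block called 7 early nodulation and infection genes higher, including the 6, and also a fall of 1 gene each in the Nod factor, autoregulation and further receptor lists, and a rise of 1 gene in the last. Leaving out inoculated without salt A, B or C gave 166, 87 or 191 higher genes, and B or C 131 or 125 lower ones. Leaving out inoculated with salt A or C gave 132 or 149 higher genes, and A, B or C 159, 132 or 122 lower ones. Without mock without salt B, 192 were lower. DESeq2 called 925 higher and 675 lower, and 4131 genes had an unadjusted edgeR p under 0.05.

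Salt moved many of the same genes in mock and inoculated roots, more than independent lists would share. Of the 79 genes higher with salt in mock roots, 54 were also called higher in inoculated roots, where independent lists would share 1.22 (Fisher's exact test, p = 3.3e-80). Of the 71 lower genes, 58 were shared, against 0.899 for independent lists (Fisher's exact test, p = 1.06e-99). All 79 and all 71 had the same sign in inoculated roots, with median log2 changes of 1.12 and -1.13 (camera p = 0.000614 and 7.78e-07 with an estimated correlation). These contrasts have no library in common. Deviations of same-letter mock and inoculated libraries still correlated, at 0.234 to 0.399 with salt and 0.0693 to 0.524 without. The contrasts can therefore share error, which Fisher's test on independent lists does not allow for. Across all genes, which are not independent replicates, the log2 changes correlated with r = 0.474 (rho = 0.423). The counts of shared genes depended on single libraries of both comparisons. Without mock without salt A, B or C they were 8, 10 or 5 higher and 16, 8 or 10 lower, and without mock with salt A or C 23 or 4 higher, with 7 lower without C. Without inoculated without salt B or C they were 35 or 17 higher, with 29 lower without C, and without inoculated with salt C 22 were higher.

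The rhizobium effect without salt gave the response to the bacteria at 24 hours under ordinary growth conditions. The early nodulation and infection list was higher as a whole after inoculation, with 18 of 24 tested genes positive and a median log2 change of 0.51 (camera adjusted p = 4.32e-29, and adjusted p = 0.000594 with an estimated correlation). Adjusted over the list alone, 11 of its genes rose. Over all 22816 genes, 0 of them passed. Medtr6g027840 had a log2 change of 1.70 (SE 0.36; edgeR adjusted p = 0.446), with 0.632 ± 0.0922 CPM in mock and 2.09 ± 0.844 CPM in inoculated roots (SD, n = 3). Medtr3g086320 had 0 counts in mock and 47 in inoculated roots, summed over 3 libraries, which is at least 14.8-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.115). DESeq2 gave these 2 genes adjusted p of 0.0344 and 0.000882, within ranges of 0.0344 to 1 and 0.000882 to 1 over 25 alternatives each. Without the low-count filter the second had an edgeR adjusted p of 0.0430. In the Nod factor list 0 of 12 genes were called by edgeR, over all genes or over the list alone, and the list did not pass (camera adjusted p = 0.0771). It did pass without mock without salt B or C (0.00283 and 0.0107) or inoculated without salt B (0.000389).

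By edgeR 0 genes were called higher or lower for rhizobium without salt, with a smallest adjusted p of 0.0626 and 551 genes at an unadjusted p under 0.05, where chance alone gives 1141. With the replicate letter as a block, 784 genes were at that level by edgeR and 4 were called higher. Numbers under chance mean that p values ran large here, so 0 calls do not show that nothing responded. DESeq2 called 28 genes higher and 3 lower, 7 of the 28 in the early nodulation and infection list, with 534 genes at an unadjusted p under 0.05. By limma on FPKM with a pseudocount of 0.1, 6 genes were higher, and without a low-count filter edgeR called 6 higher. Without inoculated without salt A or B, edgeR called 2 or 8 genes higher.

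The rhizobium effect with salt asked the same in roots kept in 100 mM NaCl. Inoculation raised 104 genes and lowered 1. Of the 24 tested early nodulation and infection genes, 8 rose over all genes and 13 adjusted over the list alone, and the list's median log2 change was 1.89 (camera adjusted p = 3.65e-40, and adjusted p = 0.000238 with an estimated correlation). Medtr6g027840 rose by 3.97 log2 units (SE 0.35), from 0.570 ± 0.138 to 9.10 ± 2.40 CPM (SD, n = 3; edgeR adjusted p = 0.000486). Medtr3g086320 rose from 1 count to 413, summed over 3 libraries, a ratio of 403 with a 95% counting interval of 71.8 to 15936 (exact binomial, counting error only; edgeR adjusted p = 0.000486). Of the 8 genes, 5 had over 3 counts in the mock group and rose by 1.81 to 4.27. Without mock with salt A, B or C, 5, 6 or 5 of the 8 calls were kept, and 7 without inoculated with salt B. In the Nod factor list 3 of 12 genes rose, by 1.14 to 1.42, over all genes and adjusted over the list alone. These 3 calls were lost in 6, 11 and 14 of 25 alternatives. Without mock with salt A, B or C or inoculated with salt C, 0 of the 3 passed by edgeR. Without mock without salt B or C, inoculated without salt C or inoculated with salt A or B, 1 passed, and without inoculated without salt A, 2 passed. The list lay higher than other genes by camera (median 0.23, adjusted p = 2.06e-05), a call lost with an estimated correlation (adjusted p = 0.179). The 1 gene that fell, Medtr1g030810, went from 31.5 ± 4.30 to 18.1 ± 2.58 CPM (SD, n = 3), a log2 change of -0.80 (SE 0.15; edgeR adjusted p = 0.0409). It was lost in 16 of 25 alternatives, with adjusted p from 0.000230 to 0.193 over edgeR, DESeq2 and limma, and was 0.0517 with the replicate letter as a block.

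For rhizobium with salt, 2090 genes had an unadjusted edgeR p under 0.05 (1052 without mock with salt A, 4766 without mock with salt B, 1333 in the fit of the 6 compared libraries), and DESeq2 called 241 higher and 12 lower. Leaving out mock with salt A, B or C gave 41, 50 or 41 higher genes, and leaving out the resubmitted library, inoculated with salt A, gave 61. The call of the single fall, Medtr1g030810, was lost without each library in turn except inoculated without salt C, with edgeR adjusted p from 0.0521 (without inoculated without salt A) to 0.193 (without mock with salt A).

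The set of genes called with salt also lay higher without it. Of the 104 genes that rose with rhizobium in salted roots, 99 (95.2%) had a positive log2 change without salt, against 51.8% of all genes. As a set they were higher without salt by camera (p = 0.000148 with an estimated correlation) and by fry (p = 0.000660). Their medians were 0.96 without and 2.63 with salt. The latter was raised by choosing the genes in that contrast, so the medians do not compare the rhizobium effects. Since edgeR called 0 genes without salt, 0 were shared between its lists. By DESeq2, 27 of the 28 genes higher without salt were also higher with salt, and 26 were among edgeR's 104. Without inoculated without salt A or B, edgeR's lists shared 2 or 7 genes. Across all genes the log2 changes correlated with r = 0.265 (rho = 0.0640), with no library in common. Same-letter deviations with and without salt correlated at 0.114 to 0.262 in inoculated and -0.134 to 0.239 in mock roots, so some error may be shared.

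The difference of the rhizobium effects, with salt minus without, tested whether salt altered the response to the bacteria, the question named in the series title. The early nodulation and infection list was higher in this contrast, with 18 of 24 genes positive and a median log2 difference of 0.61 (camera adjusted p = 0.000255). With an estimated correlation the call was lost (camera adjusted p = 0.205, unadjusted p = 0.0293), and fry gave an adjusted p of 0.147 (unadjusted p = 0.0420). Over all genes 0 of its members were called by edgeR, and 2 were higher adjusted over the list alone. Medtr6g027840 had a log2 difference of 2.27 (SE 0.51; edgeR adjusted p = 0.915, unadjusted p = 0.000886). The Nod factor list also lay higher by camera (median 0.19, adjusted p = 0.0157), with 0 members called, and was lost with an estimated correlation (adjusted p = 0.561). It was lost too without mock without salt B or C (0.208 and 0.0875), mock with salt A or B (0.0585 and 0.0517), inoculated without salt B (0.135) or inoculated with salt A or C (0.0529 and 0.123). By edgeR 0 genes of 22816 were called in either direction, with a smallest adjusted p of 0.758. At an unadjusted edgeR p under 0.05 there were 1207 genes, where chance alone gives 1141. Without mock without salt C, mock with salt B or inoculated with salt A, that unadjusted count was 699, 2299 or 782. DESeq2 called 14 higher and 1 lower, with 1198 genes at an unadjusted p under 0.05, and limma on FPKM without a filter called 7 higher and 1 lower. In counts simulated for this contrast, edgeR recovered 24% of genes changed 2-fold and 81% of genes changed 4-fold. Those genes had an average log2 CPM of at least 0 and varied independently. The rates therefore do not give the power for genes near the floor in mock roots.

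After these results were seen, the mean of the rhizobium effects with and without salt was added as a contrast. Its estimate is uncorrelated with the difference only where both effects have equal error. It called 76 genes higher and 0 lower by edgeR, 10 of them in the early nodulation and infection list. At an unadjusted edgeR p under 0.05 there were 1181 genes, where chance alone gives 1141. The 1181 became 722 without mock with salt A, 3257 without mock with salt B and 1788 without the resubmitted library. Of the 76, 71 were also called for rhizobium with salt, and the SE was larger without salt in 44, with medians of 0.49 without and 0.48 with salt. DESeq2 called 148 higher and 3 lower, and edgeR called 1 or 9 lower without mock without salt A or the resubmitted library. Of the 76 genes, 73 had a positive difference between the rhizobium effects, against 48.1% of all genes. As a set they were higher in the difference contrast (median log2 1.60, camera p = 0.00420 with an estimated correlation, fry p = 0.00427). In 25 of them a mock group held 3 counts or fewer, which leaves fitted folds undetermined. The other 51 had a median difference of 1.32 (interquartile range 0.91 to 2.04), and 50 of them were positive. In an exact two-sided permutation of the salt labels within inoculated and within mock libraries, with 400 assignments, the median difference in log2 CPM was 1.79 for the 76 genes (p = 0.005, the smallest these assignments can give) and 1.33 for the 51 genes (p = 0.01). The early nodulation and infection list, fixed in advance, had 0.43 in the same exact permutation test (p = 0.295). The permutation is exact only where salt changes nothing in mock and in inoculated roots. That null differs from equal rhizobium effects, so its p does not decide the difference. The 400 assignments also ignore the letters, which were taken to pair the inoculated libraries for salt. With exchanges only within letters in inoculated roots, 160 assignments gave exact p of 0.0125 (the smallest possible), 0.025 and 0.338 for the 76 genes, the 51 genes and the list. Within letters in mock roots too, 64 assignments gave exact p of 0.0312 (the smallest possible), 0.0312 and 0.312.

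**Figure D2:**
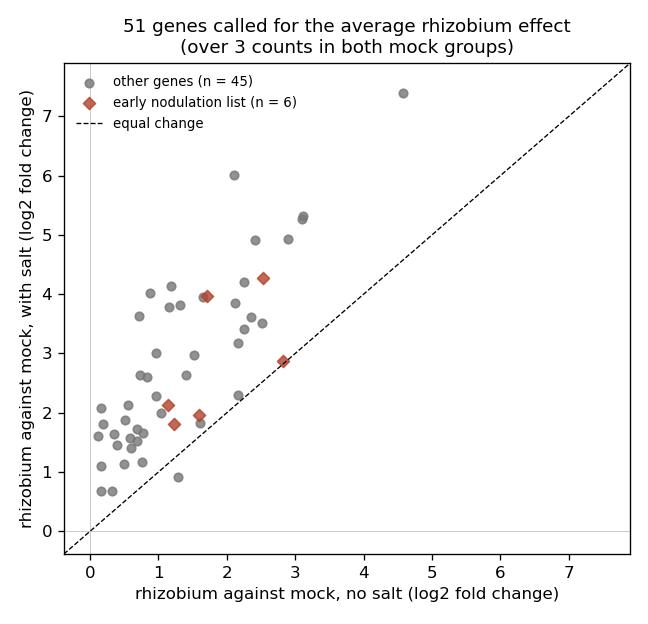
Log2 fold change of rhizobium against mock without salt (horizontal) and with salt (vertical) for the 51 genes called for the average rhizobium effect with over 3 counts in both mock groups, each point 1 gene. The dashed line marks equal change, and 50 of the 51 genes lie above it. The early nodulation list members (red diamonds) lie at unlike distances above it. Medtr5g099060 is close to the line (2.82 without and 2.88 with salt) and Medtr6g027840 far from it (1.70 and 3.97).

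The plot of levels per library shows the same 51 genes. Their median log2 level over the mock libraries of the same salt condition was 1.49, 0.63 and 1.11 in inoculated roots without salt A, B and C, and 2.65, 2.19 and 2.29 in those with salt. Mock libraries lay between -0.20 and 0.10, since their own mean was subtracted. The 51 genes were chosen as higher in these inoculated libraries, so their distance from mock is no separate evidence. For the early nodulation and infection list, not plotted, the same measure was 0.55, 0.78 and 0.54 in inoculated roots without salt A, B and C. In those with salt it was 2.03, 1.47 and 1.34, and in mock libraries it lay between -0.18 and 0.20.

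**Figure D3:**
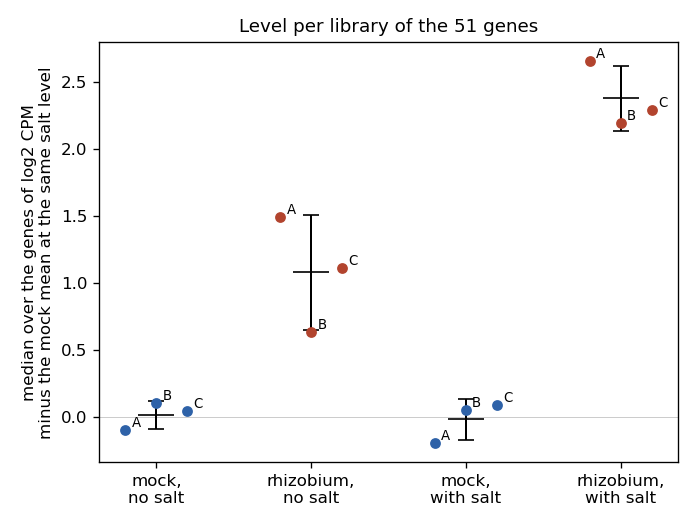
Median over the 51 genes of log2 CPM minus the mean of the mock libraries at the same salt level, for each library (points, lettered by replicate), with group mean and SD (bars, n = 3). Inoculated libraries with salt lie at 2.19 to 2.65 and those without salt at 0.63 to 1.49. The 51 genes were chosen as higher in these inoculated libraries, so their distance from mock follows from that choice.

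The lists for other organs, cell types and functions were not called by camera in any of the 5 contrasts. Leghemoglobins, the oxygen carriers of mature nodules, were mostly below the count filter, with 2 of 11 genes tested and camera adjusted p from 0.486 to 0.962. Root apical meristem genes had 5 of 5 tested, with adjusted p from 0.0924 to 0.962. Arbuscular mycorrhiza genes had 3 of 5 tested, with adjusted p from 0.0771 to 0.962. The list of further receptors, channels and nodule development genes had 7 of 10 tested, with adjusted p from 0.330 to 0.962. The autoregulation list, outside inoculated roots, had adjusted p from 0.324 to 0.621. By fry, the autoregulation list fell with salt in mock roots (adjusted p = 0.0297) and in inoculated roots (adjusted p = 0.000488). With the replicate letter as a block the fry call in mock roots was lost (adjusted p = 0.0791) and that in inoculated roots kept (0.00132). Against other genes, camera with an estimated correlation gave adjusted p of 0.578 and 0.135. The meristem list passed camera for rhizobium without salt when inoculated without salt B was left out (adjusted p = 0.0283) and for the difference when mock with salt A was left out (0.0322). The mycorrhiza list passed for rhizobium without salt when mock without salt C (0.0486) or inoculated without salt A (0.0304) was left out.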

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

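The contrast of the average rhizobium effect, the set of genes it called, the permutations of salt labels, the splits within letters, the restriction to 51 genes and the tests of scaling and of added amounts were chosen only after the results were seen, while the early nodulation list and its test in the difference contrast were planned.

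The rhizobium-responsive genes are the subject of the series title. The 76 called for the average rhizobium effect changed more with salt than without in a test of the difference itself (camera p = 0.00420 with an estimated correlation, unadjusted). After adjustment over the lists, the planned early nodulation and infection list passed only at the preset correlation (camera adjusted p = 0.000255). With an estimated correlation its camera adjusted p was 0.205 (unadjusted p = 0.0293), and its fry adjusted p was 0.147 (unadjusted p = 0.0420). A single library carrying the difference is argued against by the median log2 difference of the 51 of the 76 genes with over 3 counts in both mock groups. It was 1.17 at its lowest, without inoculated without salt B, and 1.23 without the resubmitted library (1.26 and 1.66 for the genes called anew in those fits). The scaling of the libraries, which shifts all genes of a library alike, is argued against by the median of the 51 genes lying 1.33 above that of all tested genes (their lower quartile 0.92 above), and an equal added amount over a lower mock level by the CPM gain over mock, which with salt was a median 4.19 times that without for the 76 genes and 3.96 times for the 51. A stronger response to the bacteria in salted roots is a candidate explanation and remains a hypothesis. The per-gene test of the difference called 0 genes by edgeR against 14 higher and 1 lower by DESeq2. At an unadjusted edgeR p under 0.05 there were 1207 genes, where chance alone gives 1141. The planned list did not pass the exact permutation of salt labels (p = 0.295), which is exact only where salt changes nothing in either kind of root. That list's median log2 level over mock was 0.54 to 0.78 in inoculated libraries without salt and 1.34 to 2.03 in those with salt. Whether the extent or timing of infection, bacterial numbers or root growth differed with salt was not analysed here, so no mechanism was tested.

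Other assignments of the libraries to groups were tried for each count of called genes. Exchanging labels between the compared groups allows 10 splits, too few for a share under 0.05. The real split called 150 genes for salt in mock roots, 105 for rhizobium with salt and 640 for salt in inoculated roots, and the highest of the other splits called 0, so 1 of the 10 splits was as large in each. The splits that part the same letters gave 0 as well in the contrasts where letters were taken to pair the samples. For rhizobium without salt the real split and the highest other both called 0 by edgeR (551 at an unadjusted p under 0.05, and 28 higher and 3 lower by DESeq2). For the difference of the rhizobium effects, 60 of 200 possible splits were drawn. The real one called 0 by edgeR and the highest other 56. At an unadjusted edgeR p under 0.05 the real split had 1207 genes, where chance alone gives 1141. DESeq2 called 14 higher and 1 lower for it. A count of 0 is reached by every split, so the 10 of 10 and 60 of 60 as large say nothing about chance. These splits also keep part of the real rhizobium effects: the highest exchanged 1 pair of labels without salt and 0 with salt. For the average rhizobium effect 1 of the 60 was as large, the real one with 76 genes against a highest other of 56. These splits ignore the letters, which were taken to pair the samples for rhizobium with salt. With labels exchanged only within letters among the libraries with salt, 1 of the 80 splits was as large (highest other 56). Within letters at both salt levels it was 1 of the 32 (highest other 18). These are the smallest shares such splits can give, and other splits keep part of the real effects. The contrast and the splits within letters were also chosen after the results were seen, so chance is not excluded.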

How the results depend on the processing

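The tests of the average rhizobium effect, of the genes it called and of the overlap of the salt responses given here were chosen after the results were seen. No result reversed. The upper-quartile and DESeq2 scalings, the stricter filter and the robust fit left every count within 1.5 times its main value. Counts below are higher and lower genes, and the cause was not tested unless a smaller number of libraries or a stricter threshold is itself the change.

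DESeq2 called 378 and 328 genes for salt in mock roots, 28 and 3 for rhizobium without salt, 241 and 12 for rhizobium with salt, 925 and 675 for salt in inoculated roots, 14 and 1 for the difference and 148 and 3 for the average rhizobium effect. Its rhizobium lists shared 27 higher genes, and its salt lists 195 higher and 224 lower. At an adjusted p under 0.01, edgeR called 6 and 6 for salt in mock roots, 54 and 0 for rhizobium with salt, 23 and 26 for salt in inoculated roots and 44 higher for the average, with 4 and 5 shared by the salt lists. At least a 2-fold change left 45 lower in mock and 141 lower in inoculated roots with salt, 0 lower for rhizobium with salt, and 33 and 34 shared by the salt lists. The fit of the 6 compared libraries, with fewer residual degrees of freedom, called 90 and 106 for salt in inoculated roots and 0 lower for rhizobium with salt, with 15 and 14 shared by the salt lists. Without a low-count filter 6 genes were higher for rhizobium without salt, and 6 were shared with the list with salt.

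Limma on log2(FPKM + 0.1) called 6 higher for rhizobium without salt (6 shared), 64 higher for rhizobium with salt and 229 higher for salt in inoculated roots. Limma on log2(FPKM + 1) called 3 lower for rhizobium with salt. Without its filter it called 45 and 45 for salt in mock roots, 1 lower for rhizobium without salt, 7 lower for rhizobium with salt, 221 and 161 for salt in inoculated roots, 7 and 1 for the difference and 3 lower for the average, with 27 and 32 shared by the salt lists. For the early nodulation list in the difference, the adjusted p of 0.000255 became 0.205 with an estimated correlation and 0.147 by fry.

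The replicate block, with the letter as a term, called 636 and 593 genes for salt in inoculated roots, where letters were taken to pair the samples. For rhizobium with salt, where they were also taken to pair them, it called 123 higher, with 99 of the 104 shared. It also called 1 lower, another gene than Medtr1g030810 (edgeR adjusted p = 0.0517). In the early nodulation and infection list it called 10 genes higher against 8 for rhizobium with salt, and 7 against 6 for salt in inoculated roots. Where the rule for pairing was not met it called 241 and 235 for salt in mock roots and 4 higher for rhizobium without salt, 4 of which were shared with the list with salt. The block's salt lists shared 139 and 177 genes. Correlations between same-letter libraries ran from -0.134 to 0.239 for salt in mock roots, with 3 of 6 libraries closest to their own letter, and from 0.0693 to 0.524 for rhizobium without salt, with 4 of 6. This is a hint from the data and not from the design.

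With each of the 12 libraries left out in turn, salt in mock roots gave 5 (without mock with salt C) to 177 higher genes (without mock with salt B) and 7 (without mock with salt C) to 95 lower. Rhizobium without salt gave 0 to 8 higher (without inoculated without salt B). Rhizobium with salt gave 41 (without mock with salt A or C) to 115 higher and 0 to 1 lower. Salt in inoculated roots gave 87 (without inoculated without salt B) to 435 higher and 122 (without inoculated with salt C) to 375 lower. The average rhizobium effect gave 0 to 9 lower (without the resubmitted library). Shared genes ran from 0 to 7 for the rhizobium lists and from 4 to 68 higher and 7 to 63 lower for the salt lists. The difference gave 0 by edgeR in all 12, with 699 (without mock without salt C) to 2299 genes (without mock with salt B) at an unadjusted p under 0.05, against 14 higher and 1 lower by DESeq2 with all libraries, and the early nodulation list had a camera adjusted p of 3.66e-06 to 0.0114 in it at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.205) and by fry (0.147) with all libraries.

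Of the list results under the alternatives, 616 stayed on their side of the threshold, 17 lost and 13 gained a call. These numbers leave out the early nodulation list in the difference, given above. For single genes the numbers were 1784, 149 and 66. These genes were list members with an unadjusted edgeR p under 0.05 and some of the largest changes by the rule. Depth limits genes near the floor of 3 counts, including 25 of the 76 genes called for the average rhizobium effect.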

Other observations

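The average salt effect and the tests on it were all chosen after the results were seen, and were run by edgeR alone with no library left out.

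Averaged over mock and inoculated roots, salt raised 691 genes and lowered 778 of 22816 tested. With the replicate letter as a block these numbers were 970 and 1125, with 681 and 768 shared. In the Nod factor perception and common symbiosis signalling list, 1 gene rose and 3 fell, over all genes and adjusted over the list alone, and the list as a whole did not stand apart (camera adjusted p = 0.325). In the early nodulation and infection list 5 genes rose by 0.45 to 1.68 log2 units, 6 adjusted over the list alone, again without the list passing (camera adjusted p = 0.114). Of the 4 genes on autoregulation and systemic control of nodule number, 1 fell by 0.82 log2 units, and all 4 were negative. That list moved as a whole by fry (adjusted p = 0.000294) and did not pass against other genes (camera adjusted p = 0.114, and adjusted p = 0.331 with an estimated correlation). Among further receptors, channels and nodule development genes, 1 rose and 1 fell (camera adjusted p = 0.411). In the difference of the rhizobium effects, which is also that of the salt effects, the 691 lay higher and the 778 lower than other genes by camera (p = 8.94e-05 and 0.000286), calls lost with an estimated correlation (p = 0.185 and 0.149).

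The 76 genes called for the average rhizobium effect were read for salt alone. In mock roots 0 were called higher and 1 lower with salt by edgeR, and the 51 with over 3 counts in both mock groups had a median log2 change of -0.22 (interquartile range -0.56 to 0.27). In inoculated roots 32 of the 76 were called higher with salt, which is not independent of how they were chosen, since those libraries entered the choice.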
